A study of Arabidopsis thaliana with 12 samples.

How the data were processed

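RNA-seq was made by the submitters from 12 libraries of whole seedlings, 2 replicates in each of 6 groups: Col-0, smeb-1 and smeb-2 at 22 °C and at 4 °C for 24 h. The labels describe the control both as 22 °C for 24 h and, in the treatment protocol, as 0 h at 4 °C. Per the submitters' processing notes, Trimmomatic 0.32 and TopHat2 2.0.13 were used with the TAIR10 genome build. The tool that called and tested the splicing events, its filters, the handling of strand and the way in which alleles and replicates were combined are not given in the sources used here.

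The deposited data are 7 tables. The event tables cover smeb under normal conditions, smeb under chilling and Col-0 under chilling, and each event has a gene, a position, a kind and a pair of p-values that the authors headed adjusted P value and FDR per the file headers. A list of SmEb-dependent and a list of SmEb-independent genes have the same columns without position, and 2 further tables give enriched gene ontology terms with the p-value, adjusted p and q-value that the authors deposited. No column holds values per sample, counts, effect sizes or a direction, so no test across samples was run, no standard deviation could be given, and the depth per sample and the precision it gives are unknown. An event that is not listed can have been tested and not called, or not tested.

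The design fixed beforehand assumed fold changes and ranked genes by them. With none in the tables, the calls were counted without direction and genes were named by the lowest FDR, with ties by the number of events and then by locus: up to 16 genes with a reference symbol per table, up to 3 called members of each gene list, and SmEb, SmEa and HAB1. Of lists of which 5 or more genes were called, every called member was named, and events were singled out for their position or class; both choices were made after the values were seen. In the table at 22 °C, 21 of 55 rows repeat another row and were counted once.

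Positions are those of the authors' tables, 1-based, on TAIR10. The reference annotation of the TAIR10.1 assembly (38094 genes, 27562 of them protein-coding and 24229 with an annotated intron) uses compatible coordinates: of the 1891 events in either chilling table, 1834 (97.0%) lie inside the listed gene, and 327 of 425 retained introns (76.9%) match an annotated intron when 1 base is taken off at each end of the listed interval. Of the 1140 Col-0 genes, 1139 were found in the reference. Of the 425 retained introns, 43 read GT to AG only on the strand opposite to the listed gene, which leaves their gene uncertain. Exon and intron numbers follow the first annotated transcript by name that holds the feature. An exon was taken as always included where it is annotated and no annotated intron of the gene spans it.

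Genes and events of the tables were compared as sets with Fisher's exact test (two-sided, sample odds ratio with a 95% log interval after adding 0.5 to each cell), with the expected overlap of independent lists. Events were taken as identical where gene, kind and position agreed. The comparisons of single events, their kinds and their properties were not part of the design and were chosen after seeing the data. Gene lists were tested against all annotated genes with Benjamini-Hochberg adjustment over 17 lists and 3 tables, event kinds over 8 kinds, and properties of events over 16 tests. Medians of lengths were compared with a permutation test of 100000 draws. Genes in 1 list and events in 1 table are not independent replicates, and paralogs can share events. The p-values of these tests do not measure the spread between libraries.

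The number of events tested was recovered from the p-values and FDR values that the authors deposited. Under the Benjamini-Hochberg rule, the ratio of the pair multiplied by the number of tests is the rank. Only events with a p-value above 0 were used. Once the right number is used, the rank is whole within a tolerance of 0.0001 for 88.4% of these events in smeb, 85.3% in Col-0 and 87.0% at 22 °C. The procedure gave 10308, 9710 and 10657 tested events, with the last listed event at rank 1693, 1346 and 43. The procedures were tested on simulated data: 7 of 100 pairs of independent lists of the sizes of the Col-0 and smeb gene lists, drawn from 24229 genes, had p under 0.05, lists of 100 genes with a simulated odds ratio of 5 had a median recovered odds ratio of 4.81, and the number of tests and last rank were recovered in 3 of 3 simulated tables. In those tables the last called event was always kept, so the last rank followed from the number of tests and was not tested separately.

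Alternatives were an FDR under 0.01, protein-coding genes or the union of all listed genes as background, lists rebuilt from the chilling tables (without the sign of the change, which the tables lack) and genes that occur once in each table, chosen before the data were examined, and further ones chosen after seeing the data, such as an FDR under 0.001, 1 event per gene and overlap of positions. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.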

Results

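RNA was sequenced from whole Arabidopsis thaliana seedlings, 12 days old, of the wild type Col-0 and of 2 mutants, smeb-1 and smeb-2. Both mutants carry a lesion in SmEb (AT2G18740), which encodes an Sm core protein, a subunit of the ring of proteins that holds the small nuclear RNAs of the spliceosome. Each of the 3 genotypes was sampled at 22 °C and after 24 h at 4 °C, which makes 6 groups of 2 replicates and 12 libraries. The labels do not say whether replicates came from separate cultures. The measurements reported here are splicing events in the authors' deposited tables, each with a position, a kind and a false discovery rate (FDR). Neither the size and direction of a change nor any read count stands beside an event, so the depth is unknown, and an event is described as called or listed, never as higher or lower.

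The first comparison concerns splicing in wild-type seedlings under chilling; the table does not state the groups it sets against each other. In Col-0, 1339 events in 1140 genes were called, and genes that act in splicing themselves and genes of the circadian clock stood among them. MAP65-8 (AT1G27920), a microtubule-associated protein, had 7 events listed, the highest number for any gene, and GRP7 (AT2G21660), a glycine-rich RNA-binding protein under clock control, had 5. The retained intron of MAP65-8 reads GT to AG only on the opposite strand, and none of its alternative splice sites has both positions annotated. The gene that holds the 7 events is therefore uncertain. ATU2AF65A (AT4G36690), the large subunit of the factor that recognises the polypyrimidine tract at 3′ splice sites, had 3 events at an FDR of 0 in the authors' deposited table. U1-70K (AT3G50670), a protein of the U1 small nuclear ribonucleoprotein, had its intron 6 (909 nt, chromosome 3, 18827440 to 18828348) called as retained at an FDR of 0 in the authors' deposited table. ACHT4 (AT1G08570), a thioredoxin of plastids, CLPX (AT5G53350), a subunit of the mitochondrial Clp protease, and the kinase CIPK3 (AT2G26980) also had events at an FDR of 0 in the authors' deposited table. So did the polyubiquitin gene UBQ10 (AT4G05320), the transporter gene UMAMIT44 (AT3G28130), RLM3 (AT4G16990), a disease resistance protein, the inositol phosphate kinase IPK2a (AT5G07370), the SR-like protein ATSRL1 (AT5G37370), the sterol glucosyltransferase UGT80B1 (AT1G43620), SOFL1 (AT1G26210) and UAP56b (AT5G11200), an RNA helicase of splicing and export. Some of the 5 events listed for UAP56b lie in its near-identical neighbour.

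Of the Col-0 events, 388 (29.0%) were alternative 3′ splice sites, 286 (21.4%) retained introns, 284 (21.2%) cassette exons and 266 (19.9%) alternative 5′ splice sites. Alternative starts, ends, multiple cassettes and mutually exclusive exons made up the rest. In all, 150 genes had more than 1 event. The FDR in the authors' deposited table was 0 for 247 events and under 0.01 for 945. The retained introns listed for MAP65-8 and SOFL1 read as introns (GT at the start, AG at the end) only on the strand opposite to those genes, so the gene that holds each is uncertain.

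For the mutants under chilling, 1359 events in 1097 genes were called; whether these are changes against smeb at 22 °C or against chilled Col-0 is not stated. Many of the leading genes were those of Col-0. MAP65-8 again had the same 7 events, whose gene is uncertain. GRP7 and ATU2AF65A had 4 each, and the serine/arginine-rich (SR) splicing factor SR34 (AT1G02840) had 2. SR30 (AT1G09140), another SR splicing factor, had a cassette exon (chromosome 1, 2943418 to 2943564) and an alternative 3′ splice site called at an FDR of 0 in the authors' deposited table for smeb and was not listed for Col-0. RABG3B (AT1G22740), a small GTPase of the endomembrane system, also had 2 events in smeb and none in Col-0. ERD10 (AT1G20450), a dehydrin induced by cold, had 3 events in smeb, of which 1, a stretch of 41 nt that is not an annotated intron, was listed in Col-0 too. Further genes with an event at an FDR of 0 in the authors' deposited table for smeb were PTM (AT5G35210), RCD1 (AT1G32230), NET1D (AT1G03080), an actin-binding protein, PRP39 (AT1G04080), a U1-associated splicing factor, UMAMIT44, RLM3, IPK2a, ATSRL1 and UGT80B1, all of which were listed in Col-0 as well.

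Of the smeb events, 387 (28.5%) were cassette exons, 327 (24.1%) retained introns, 307 (22.6%) alternative 3′ splice sites and 228 (16.8%) alternative 5′ splice sites. The authors' deposited table gives an FDR of 0 for 324 of these events and under 0.01 for 1069. The tables do not state which groups this comparison set against each other or how the 2 alleles were combined. The ranks behind the FDR values place the last listed smeb event at rank 1693 of 10308 tested events, so at least 334 events (19.7%) that rank above it are not listed, against 7 of 1346 (0.52%) in Col-0.

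A further table lists splicing events in smeb under normal conditions, at 22 °C; the groups it sets against each other are not stated. Here 34 events in 27 genes were listed. The last of them is at rank 43 of 10657 tested events. If each event was ranked once, at least 9 events (20.9%) that rank above it are not listed. However, 21 of the 55 rows repeat another row, and whether any repeat took a rank is unknown. RCA (AT2G39730), the activase of Rubisco, had its intron 6 (124 nt, chromosome 2, 16571067 to 16571190) called as retained at an FDR of 0 in the authors' deposited table, an event that was also called in chilled Col-0 and not in chilled smeb. RPS5A (AT3G11940), a ribosomal protein, had the intron of its 5′ UTR (85 nt) called, and LHCB4.1 (AT5G01530), a light-harvesting protein, a stretch of 24 nt. GRP7, U1-70K, UBQ10, the clock gene PRR7 (AT5G02810) and SMD1A (AT3G07590), another Sm protein, were listed as well, as were PSI-P (AT2G46820), a thylakoid protein, RPS6 (AT5G46470), a resistance protein, LpxC4 (AT1G25145), an enzyme of lipid A synthesis, and the glycine-rich protein GRP-3 (AT2G05520). The positions of both LpxC4 events (chromosome 1, 8799542 to 8800436 and 8800356 to 8800436) lie outside that gene (8818867 to 8820736), so the gene they belong to is uncertain.

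Of the 27 genes, 16 were also listed in chilled smeb and 15 in chilled Col-0 (odds ratios 49.8, 95% interval 23.1 to 104, and 41.1, 19.3 to 86, Fisher's exact test, two-sided, p = 1.9e-18 and 1.5e-16 over 38094 annotated genes), against 0.778 and 0.807 expected of independent lists. Libraries used in more than 1 of these comparisons would add to the overlap by themselves, and the tables do not say which were used. The expected counts are over all annotated genes, and genes without a tested event could be in no table, which also raises the odds ratios. The odds ratios are therefore no measure of a shared response. The other 11 genes were in neither chilling table. Of the 34 events, 11 were in the table of chilled smeb and 11 in that of chilled Col-0, with 8 in both. Only 5 of the 10 retained introns at 22 °C are annotated introns of the listed gene. Of the 10, 3 read GT to AG only on the opposite strand, among them that of EXT3 (AT1G21310), an extensin. Gene AT5G53048 (5 events) overlaps AT5G53050 (2 events), and without strand information their events cannot be assigned with certainty.

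The central question of the design is which part of the response to chilling needs SmEb. Of the 1491 genes in either chilling table, 746 were called in Col-0 and in smeb, 394 in Col-0 alone and 351 in smeb alone. With the contrast of the smeb table not stated, these counts say only in which tables a gene is listed. Among the shared genes were GRP7, GRP8 (AT4G39260), CCA1 (AT2G46830), ATU2AF65A, U1-70K and SR34. The shared genes made up 65.4% of the Col-0 and 68.0% of the smeb genes, against 32.8 shared genes expected of independent lists. The odds ratio was 198 (95% interval 168 to 232) over all annotated genes and 123 (105 to 145) over the 24229 genes with an annotated intron, and the p of Fisher's exact test was too small to be represented. Genes without a tested event could be in neither table, which raises both odds ratios.

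At the level of single events, 807 were identical in gene, kind and position, against 187 expected from the 9710 events tested in Col-0 (odds ratio 21.5, 95% interval 18.7 to 24.7). A further 46 genes were in both tables without sharing an event. PRR7 was one case, with a cassette exon of 118 nt in Col-0 (chromosome 5, 640085 to 640202) and of 47 nt in smeb (640156 to 640202) that end at the same base in an annotated intron. ELF3 (AT2G25930), a component of the evening complex of the clock, was another, with a cassette exon of 38 nt in Col-0 and of 178 nt in smeb with the same lower bound (chromosome 2, 11061296). If libraries were shared between the comparisons, chance values would be shared too and would add to these overlaps; the tables do not say.

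**Figure D1:**
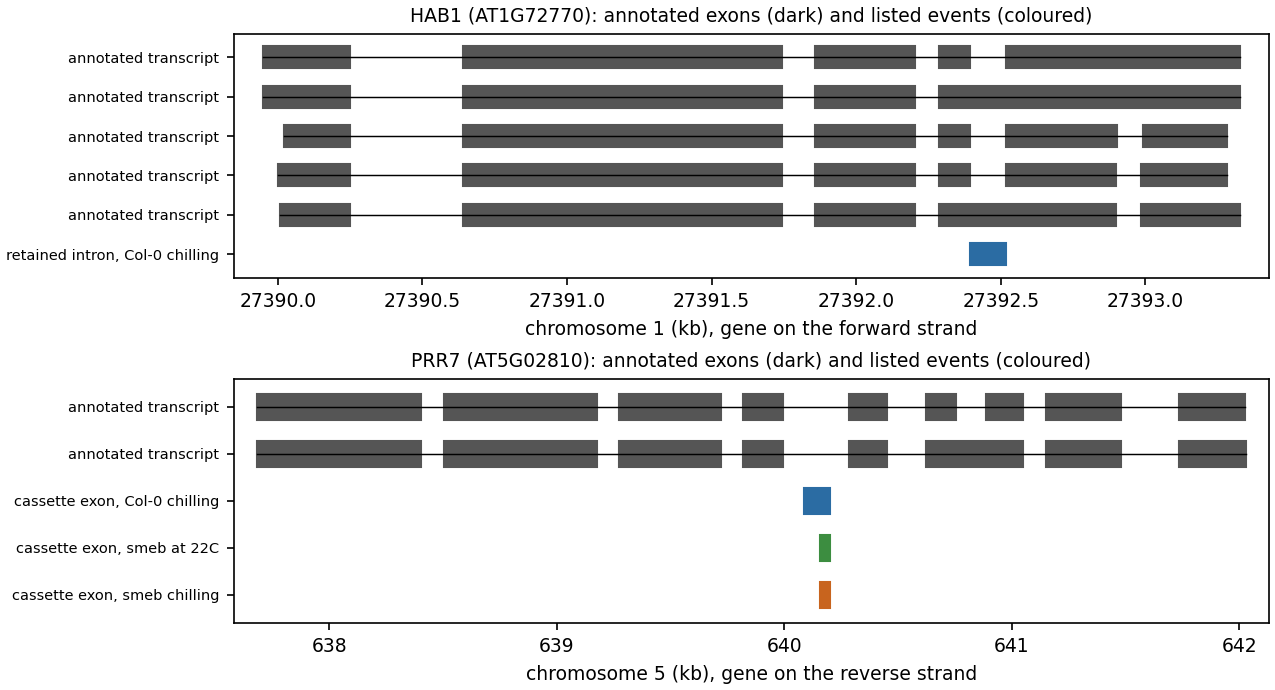
Maps of HAB1 on chromosome 1 and PRR7 on chromosome 5, with position in kb on the horizontal axis, the annotated transcripts as dark boxes (exons) joined by lines (introns), and the listed events as coloured boxes. The retained intron of HAB1 is listed for chilled Col-0 alone, and the cassette exons of PRR7 (118 nt in Col-0, 47 nt in smeb at either temperature) lie in an annotated intron and share an edge.

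The share of Col-0 events that were also listed in smeb went with their FDR. It was 87.4% (95% Wilson interval 82.7 to 91) of the 247 events at an FDR of 0 and 36.0% (31.5 to 40.9) of those between 0.01 and 0.05. In the opposite direction the shares were 79.6% and 36.6%. A gene listed in 1 genotype alone is therefore not shown to differ between genotypes, since no test of that difference is in the tables.

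**Figure D2:**
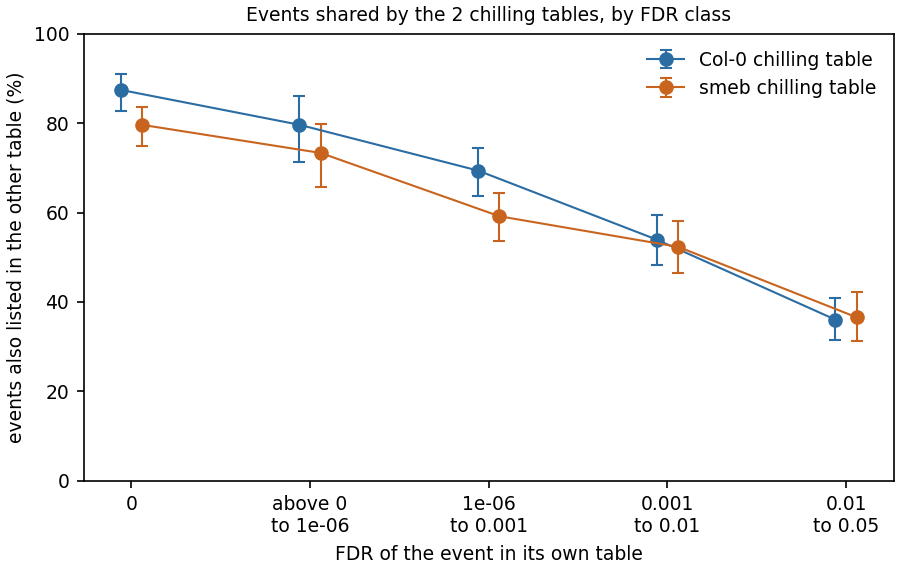
Share of events (percent, vertical axis) that are also listed in the other chilling table, by the event's FDR class in its own table (horizontal axis), for the Col-0 and the smeb table. Points are shares and bars 95% Wilson intervals; the share runs from 87.4% to 36.0% for Col-0 and from 79.6% to 36.6% for smeb.

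Genes listed in Col-0 alone included HAB1 (AT1G72770), a protein phosphatase that restrains abscisic acid signalling. Its intron 4 (123 nt, chromosome 1, 27392394 to 27392516, within the coding span) was called as retained at an FDR of 0.0117 in the authors' deposited table. By FDR, the leading genes with a symbol were ACHT4, the acetyltransferase NSI (AT1G32070), PIF5 (AT3G59060), a transcription factor that binds phytochrome, the glucosidase BGLU9 (AT4G27820) and PRP4 (AT4G38770), a proline-rich protein. All 5 had an event at an FDR of 0 in the authors' deposited table, although the 45-nt stretch in PRP4 reads GT to AG only on the opposite strand. LHCB2.1 (AT2G05100), SR45a (AT1G07350), the brassinosteroid factor BES1 (AT1G19350) and the heat shock factor HSFA1D (AT1G32330) followed, with BPM3 (AT2G39760), an adaptor of ubiquitin ligases, the acid phosphatase PAP26 (AT5G34850), the plastid protease DEG8 (AT5G39830), the carbonic anhydrase BCA6 (AT1G58180), SCPL13 (AT2G22980), the B-box factor LZF1 (AT1G78600) and the fumarase FUM2 (AT5G50950). SmEb and its paralog SmEa (AT4G30330) were in none of the tables.

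Genes listed in smeb alone included, besides SR30 and RABG3B, the calcium pump ACA10 (AT4G29900), GP ALPHA 1 (AT2G26300), the alpha subunit of the heterotrimeric G protein, and NUC1 (AT1G48920), a nucleolin. PETC (AT4G03280), the Rieske protein of the cytochrome b6f complex, had its intron 1 (91 nt) called, and P5CS1 (AT2G39800), an enzyme of proline synthesis, its exon 3 (104 nt, chromosome 2, 16602269 to 16602372). Retained introns were also called in the calpain DEK1 (AT1G55350), the corepressor SLK2 (AT5G62090), AFP3 (AT3G29575), which binds transcription factors of abscisic acid signalling, PUR5 (AT3G55010), an enzyme of purine synthesis, the polyubiquitin gene UBQ14 (AT4G02890) and the importin IMPA-2 (AT4G16143). Cassette exons were called in the zinc transporter ZAT (AT2G46800) and the ubiquitin ligase XBAT35 (AT3G23280).

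The authors' SmEb-dependent list (394 genes, 420 rows) held exactly the genes listed in Col-0 alone. Their SmEb-independent list (352 genes, 383 rows) held the 351 genes listed in smeb alone and AT2G39725, which is in neither table; none of the 746 genes called in both genotypes was in it. The median FDR was 0.00946 in the authors' deposited table of dependent genes and 0.00266 in that of independent genes. Of the dependent genes, 187 had no event under an FDR of 0.01, and 95 had an event under 0.001. With an FDR under 0.01 asked of Col-0 alone, the dependent genes numbered 207.

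The kinds of events differed between the events listed in 1 genotype alone. Events are the units of these tests, so the p-values do not measure the spread between libraries. The mutants have 4 libraries per temperature and Col-0 has 2, so the 2 tables may differ in power. By their ranks, at least 334 smeb events passed the FDR limit and are not listed. Of these, 64 had an FDR up to 0.00161 and 159 up to 0.0127. Their kinds are unknown, as is whether another filter removed them. Some events counted here as Col-0 alone can therefore have passed the FDR limit in smeb, and those of smeb alone can be incomplete. Alternative 3′ splice sites made up 33.5% of the 532 events listed only in Col-0 and 97 of the 552 listed only in smeb, a difference of 15.9 percentage points (95% interval 10.8 to 21; Fisher's exact test, two-sided, adjusted p = 9.4e-09 over 8 kinds). Cassette exons made up 16.7% and 34.8% (-18.1 percentage points, -23.1 to -13.0; Fisher's exact test, adjusted p = 9.8e-11). There were 121 alternative 5′ splice sites in Col-0 alone and 83 in smeb alone (7.71 percentage points; Fisher's exact test, adjusted p = 0.0037), and retained introns made up 18.4% and 25.2% (-6.76 percentage points, adjusted p = 0.016). By Fisher's exact test over the complete tables, the shares of alternative 3′ splice sites (adjusted p = 6.1e-04) and of cassette exons (adjusted p = 1.0e-04) also differed, while those of alternative 5′ splice sites (adjusted p = 0.11) and retained introns (adjusted p = 0.196) did not pass. Among events with an FDR under 0.001, the differences in alternative 3′ splice sites (8.81 percentage points, adjusted p = 0.092) and cassette exons (adjusted p = 0.13) no longer passed by Fisher's exact test.

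The share of always-included exons differed among cassette events, with the same limits from unlisted smeb events and from events as the units of the test. In 108 of 192 listed only in smeb (56.2%, 95% Wilson interval 49.2 to 63.1), the exon is annotated and no annotated transcript of the gene skips it, against 17 of 89 (19.1%, 12.3 to 28.5) found only in Col-0 and 43 of 195 (22.1%, 16.8 to 28.4) found in both. The exon itself is annotated in 147 of 192, 43 of 89 and 125 of 195 of these events, so part of the difference lies in exons that are not annotated. Among annotated exons, 108 of 147 in smeb alone and 17 of 43 in Col-0 alone are always included. For the shares of all cassette events, smeb alone against Col-0 alone, the adjusted p was 5.7e-08 (Fisher's exact test, two-sided, 16 tests). Such always-included exons were called in smeb for exon 6 of GP ALPHA 1 (78 nt, chromosome 2, 11198796 to 11198873), exon 16 of ACA10 (56 nt, chromosome 4, 14615249 to 14615304), exon 12 of CVL1 (AT2G32010), a phosphatase of inositol phosphates, and exon 2 of AGK2 (AT3G57550), a guanylate kinase. Cassette exons found only in smeb also lay within the coding span more often, 81.2% against 62.9% (Fisher's exact test, adjusted p = 0.0128), a difference that did not pass among events with an FDR under 0.001 (15.5 percentage points, unadjusted p = 0.094).

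**Figure D3:**
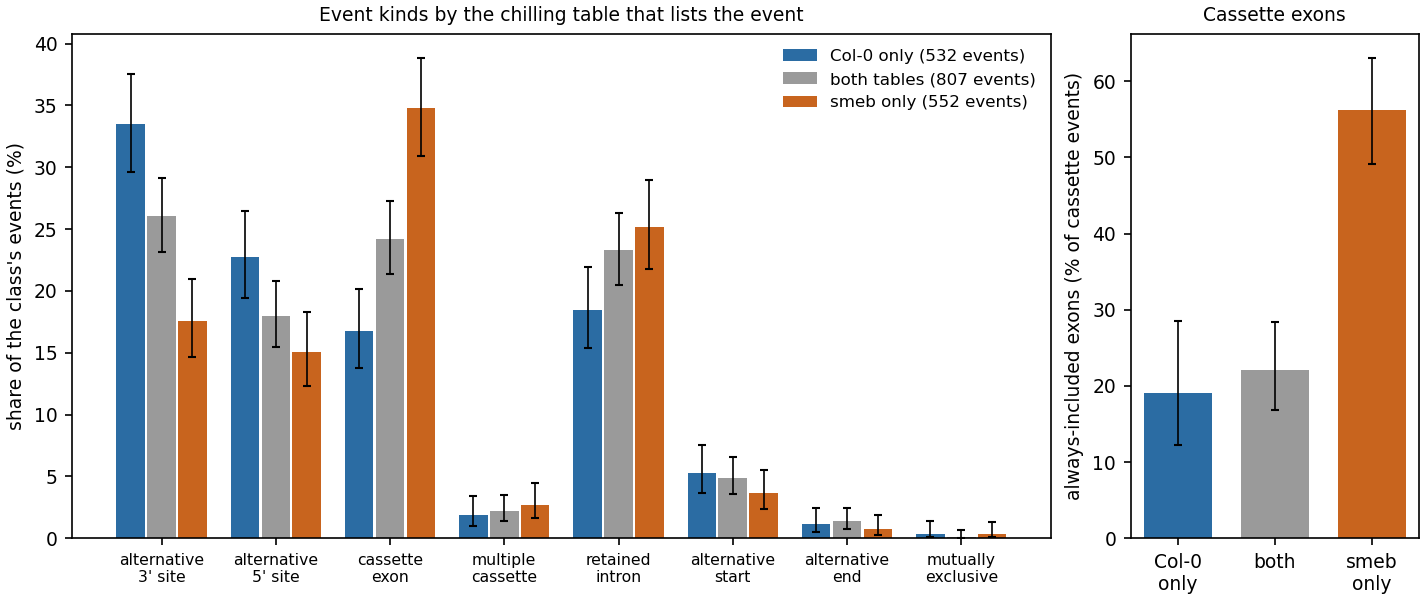
Left, share of events (percent, vertical axis) of each kind among events listed in chilled Col-0 alone (532), in both tables (807) and in chilled smeb alone (552). Right, share of cassette events (percent) whose exon is annotated and is skipped by no annotated transcript. Bars show shares and lines 95% Wilson intervals; the right panel runs from 19.1% in Col-0 alone and 22.1% in both to 56.2% in smeb alone.

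Retained introns found only in Col-0 had a median length of 111 nt and those found only in smeb of 95 nt (permutation test of the medians, two-sided, 100000 draws, adjusted p = 0.0236), a difference that did not pass with 1 event per gene (-9 nt, p = 0.125). The shift between alternative 3′ splice sites had a median of 19 nt in Col-0 alone and 25 nt in smeb alone (permutation test, adjusted p = 0.588). The shares of cassette exons, retained introns and splice site shifts with a length divisible by 3 did not differ detectably either; for cassette exons they were 40.4% and 30.7% (Fisher's exact test, adjusted p = 0.338).

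Of the 17 gene lists fixed beforehand (222 genes), the circadian clock stood out. In Col-0, 10 of its 17 genes were called, against 0.508 expected (odds ratio 46.8, 95% interval 17.9 to 117; Fisher's exact test, two-sided, adjusted p = 4.5e-10 over 51 tests), and in smeb 9 (odds ratio 38.2, adjusted p = 6.6e-09). The expected count is over all 38094 annotated genes, while 9710 events were tested in Col-0. Genes without a tested event could not be called, and which genes those are is unknown. The odds ratios of this and the other lists therefore also measure having a tested event. Called in both genotypes were CCA1, a MYB factor of the morning loop, the pseudo-response regulators PRR5 (AT5G24470), PRR7 and PRR9 (AT2G46790), ELF3, RVE4 (AT5G02840), COR27 (AT5G42900), GRP7 and GRP8. COR28 (AT4G33980), the relative of COR27, was called in Col-0 alone. LHY, TOC1, GI, LUX, ELF4, RVE8 and FKF1 were in neither chilling table.

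The list of Sm, Lsm and SR proteins also passed, through its SR proteins alone, with 5 of 17 genes called in each genotype against 0.508 and 0.49 expected (odds ratios 13.6 in Col-0 and 14.1 in smeb; Fisher's exact test, adjusted p = 9.2e-04 each). Over genes with an annotated intron the odds ratios were lower, 8.53 in Col-0 and 8.86 in smeb (Fisher's exact test, adjusted p = 0.0072 each). For the clock list they were 34.3 and 27.4. None of its 10 Sm and Lsm genes was in a chilling table. The list does not hold every such gene: LSM3A, which is outside it, was listed in chilled smeb alone. SR34, RS31 (AT3G61860), RS40 (AT4G25500) and RS41 (AT5G52040) were called in both, SR45 (AT1G16610) in Col-0 alone at an FDR of 0.0455 in the authors' deposited table, and SR30 in smeb alone. RS31, RS40 and RS41 each had a long cassette exon of 393, 257 and 326 nt, with the same bounds in both genotypes.

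The lists of cold acclimation did not pass the test. Of 18 CBF regulon and COR genes, 3 were called in each genotype, against 0.538 expected in Col-0 and 0.518 in smeb (odds ratios 6.5 and 6.76; Fisher's exact test, adjusted p = 0.0881 each), the galactinol synthase GOLS3 (AT1G09350), ERD10 and COR15A (AT2G42540), the last with its intron 3 (69 nt). Among 12 early cold-responsive transcription factors, 1 was called in each (0.359 and 0.346 expected), HSFC1 (AT3G24520), which overlaps an antisense gene, so that its events are uncertain. Only 3 of these 12 factors and 14 of the 18 CBF regulon and COR genes have an annotated intron, which leaves little room for calls in the others. Over genes with an annotated intron, 1 of the 3 factors was called in each genotype against 0.140 and 0.135 expected. Neither list passed there (Fisher's exact test, adjusted p = 0.455 for the factors and 0.143 for the CBF list, in each genotype). Of 24 genes of abscisic acid signalling, 3 were called in Col-0 (ABF2, AT1G45249, ABF3, AT4G34000, and HAB1) and ABF2 and ABF3 in smeb, against 0.718 and 0.691 expected (Fisher's exact test, adjusted p = 0.157 and 0.514).

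The remaining lists did not pass in either chilling table. Light harvesting and carbon fixation had 3 of 20 genes in Col-0 (RCA, RBCS1A, AT1G67090, and LHCB2.1) and 2 in smeb, RCA and RBCS1A (Fisher's exact test, adjusted p = 0.106 and 0.408), although the introns listed for RBCS1A are not annotated. RNA chaperones and ribosome biogenesis had 2 of 11 in each, with the helicase RCF1 (AT1G20920) in both, APUM23 (AT1G72320) in Col-0 alone and NUC1 in smeb alone. Flavonoid synthesis had 1 of 13 in each, FLS1 (AT5G08640). Auxin response had 1 of 14 in Col-0, PIF5, and sugar and proline metabolism 1 of 8 in smeb, P5CS1. The other 7 lists had no gene in either table: heat shock proteins (12 genes), salicylic acid and defence (17), jasmonate (9), glucosinolates (15), flowering time (5), root markers (8) and seed markers (2). Only 6 of the heat shock genes have an annotated intron. At 22 °C, 2 clock genes (GRP7 and PRR7) and 2 of light harvesting and carbon fixation (RCA and LHCB4.1) were listed (Fisher's exact test, adjusted p = 9.2e-04 each), and SMD1A of the Sm, Lsm and SR list (adjusted p = 0.0873).

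Between the authors' dependent and independent genes, the 17 lists could not be told apart by a test, because each has 0 or 1 gene in either group (Fisher's exact test, two-sided, lowest unadjusted p = 0.472). In the authors' deposited table of gene ontology terms for the dependent genes, 16 terms are given and none has an adjusted p under 0.05. The lowest in the authors' deposited table was 0.133, shared by regulation of RNA splicing (5 of 318 annotated genes, among them SR45 and SR45a) and anatomical structure arrangement (7 genes, among them BES1). In the authors' deposited table for the independent genes, 1 of 12 terms has an adjusted p under 0.05, biogenesis of ribonucleoprotein complexes (18 of 296 genes, NUC1 among them, adjusted p = 0.0407).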

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

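The comparisons of the kinds and properties of events, the test of power on splice sites alone and the tests of explanations for the 394 genes called only in Col-0 were chosen after the tables were seen. What singled out each of the following values is a tested difference between the events listed for chilled Col-0 and those listed for chilled smeb. Col-0 minus smeb, among events listed in 1 genotype alone, alternative 3′ splice sites differed by 15.9 percentage points, alternative 5′ splice sites by 7.71, cassette exons by -18.1 and retained introns by -6.76. Smeb minus Col-0, the share of always-included exons among cassette events differed by 37.1 percentage points, that of cassette exons within the coding span by 18.3 percentage points and the median length of retained introns by -16 nt. How far the smeb events that are not listed, at least 334, bear on these differences is unknown, since neither their kinds nor their genes are given.

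The difference in always-included exons, 56.2% of cassette events in smeb alone against 19.1% in Col-0 alone, was weighed first. Weak calls near the threshold are argued against by events with an FDR under 0.001, where it was 36.0 percentage points (95% interval 20.9 to 51.2), and fewer annotated transcripts by genes with at least 3, where it was 40.1 (27.4 to 52.9). If the smeb comparison only had more power for rare isoforms of every kind, events of the other kinds without an annotated isoform should be in excess as well. That excess was 6.09 percentage points (0.0355 to 12.2), below the cassette difference. Retained introns could hardly add to it, since only 5 of 98 in Col-0 alone and 5 of 139 in smeb alone are not covered by an annotated exon. For splice sites alone the excess was 9.99 (1.25 to 18.7). In Col-0 alone, 60.7% of alternative 3′ and 57.9% of alternative 5′ splice sites already lacked an annotated isoform. More power as the whole or part of the cause therefore stays open. A biological candidate explanation, an effect of the mutation on exon inclusion in the cold, was not tested, because the tables give no direction and do not state the contrast.

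The 394 genes called in Col-0 and not in smeb were weighed next. The share of Col-0 events also listed in smeb fell by 51.4 percentage points from the lowest to the highest FDR class, so calls near the threshold may be part of the cause. Whether they are the whole stays open: 95 of the genes had an event with an FDR under 0.001 in Col-0, but the FDR of these events in smeb is in no table. The recovered ranks leave at least 334 smeb events unlisted (19.7% of ranks), a lower limit. Whether these account for some or all of the genes cannot be told apart from a dependence on SmEb, which was not tested, because the genes of the unlisted events are unknown.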

How the results depend on the processing

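Alternatives on shared events, event kinds, always-included and coding exons, intron lengths, intron-containing genes, positions, repeated rows and mixed FDR limits were chosen after seeing the data. No paired analysis was possible because the tables hold no values per sample; with no levels, counts or fold changes either, the 2-fold and 4-fold limits (dependent genes included), the filters on low values and counts, the pseudocount, the replicate block, leaving out each replicate and another count test were not run. Of 60 alternative values over 21 results, 47 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. The overlap of genes had an odds ratio of 0.0649 against the union of all listed genes, reversed by construction, since almost every gene of that background is in a chilling table; the other 4 backgrounds, limits or units tried gave 21.5 to 243. Genes called in Col-0 and not in smeb numbered 257 with an FDR under 0.01 in both tables, 207 with an FDR under 0.01 in Col-0 alone and 95 under 0.001; those called in smeb and not in Col-0 numbered 154 under 0.001 in smeb. Where only the genotype's own limit was stricter, fewer events pass by construction; for the 257, the cause was not tested. The 22 °C table has 55 rows with repeats. With an FDR under 0.001, the differences (Col-0 minus smeb) in alternative 3′ splice sites of 8.81 and in cassette exons of -9.57 percentage points no longer passed, nor did that in coding cassette exons of 15.5 (smeb minus Col-0); fewer events were compared, and the cause was not tested further. The median intron length difference was -9 nt with 1 event per gene, -8 under an FDR of 0.01, -5 under 0.001 and -9.5 in genes called in 1 table only, none past the threshold; the cause was not tested. The difference in always-included exons ran from 36.0 to 40.1 percentage points over its 4 alternatives, and 6 gene list tests passed under each of 3 alternatives. The test of lists between dependent and independent genes could not pass at 0 or 1 gene per list, so its count of 0 says nothing about stability. Depth is unknown, so its limit cannot be given.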

Other observations

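The examples in this part were chosen after their values were seen, while the test of clock genes was fixed before its result. The authors' deposited tables of gene ontology terms also name groups that did not pass. For the dependent genes, the authors' deposited table gives 9 genes for the response to red or far-red light, among them the transcription factors PIF3 and PIF5 and the ubiquitin ligase COP1, at an adjusted p of 0.232. For the independent genes, the authors' deposited table gives 10 genes of ion homeostasis at an adjusted p of 0.174 and 7 of stomatal movement at 0.206, GP ALPHA 1 among the latter.

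Retained introns that read GT to AG only on the opposite strand made up 12 of 98 in Col-0 alone, 25 of 188 in both tables and 6 of 139 in smeb alone.

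A hypothesis weighed here is that clock genes are frequent among the called genes because they have many introns. Random lists matched on the number of annotated introns argue against it: none of 10000 held as many Col-0 genes as the clock list (permutation p = 0.0001, the smallest these draws can give), with a mean of 0.891 and a highest of 7 genes against 10. High expression or having a tested event, as a cause, cannot be told apart from a property of clock genes. The tables that list 10 of the 17 clock genes give neither expression levels nor the genes tested without a call. No biological explanation was tested.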
